A study of Saccharomyces cerevisiae with 15 samples.

How the data were processed

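RNA of 15 libraries of Saccharomyces cerevisiae W303 with ZPR1-AID was measured, in 5 groups of 3 libraries per the labels. The deposited table gives raw counts of reads per gene in 1 column per library, and the authors' normalized values were not used here. Per the submitters' processing notes the tools were FastQC 0.11.5, STAR 2.7.0 and DESeq2 1.34.0 with genome build R64. The step that counted reads per gene, whether it used strand, its treatment of reads with several matches, and the annotation release are not given in the sources used here. Overlapping and near-identical genes can therefore hold reads of each other.

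The table had 7127 gene rows, of which 6047 matched the R64 reference annotation by locus tag and 121 by symbol or synonym, while 959 did not match and kept their own identifiers. All columns were mapped to samples. A near-identical copy, taken as at least 95% identity over at least 50% of a gene, was found for 398 genes, and 322 overlapped another annotated gene. Coordinates are those of the R64 annotation.

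Library totals ran from 2530145 to 21282576 counts. The test was edgeR 4.0.16 (R 4.3.3, limma 3.58.1), with TMM scaling, the filterByExpr filter, 1 mean per group over all 15 libraries, the quasi-likelihood test and Benjamini-Hochberg adjustment at 0.05 within each comparison. It kept 6069 genes of the 6798 with a count, at a biological coefficient of variation of 17%. All tests were two-sided. CPM values used TMM library sizes, and log2 CPM a prior count of 1. Standard errors of fold changes were taken from the F statistic. The 7 comparisons were 3 h of 5-Ph-IAA with DMSO, each of the 4 treated groups with untreated cells, and the successive times of 5-Ph-IAA with each other. A test of any change covered untreated cells and the 3 times of 5-Ph-IAA.

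The groups, tests, gene lists, alternatives and rule for naming genes were chosen before the data were examined, apart from those said to have been added. The text names ZPR1, TEF1 and TEF2, then the 8 largest rises and 8 largest falls for 5-Ph-IAA against DMSO and the 4 largest of each for other comparisons. Each had to have an adjusted p under 0.05, a mean of at least 10 CPM over the 15 libraries, and no overlap between the 3 and 3 libraries. From each list described, up to 4 members with the smallest adjusted p and up to 2 that did not pass or went the other way were named. The 38 gene lists of known regulons, complexes and processes held 867 genes found in the table, and 3 genes stood in more than 1 list. Lists were tested with camera at a preset correlation of 0.01 between genes, then with an estimated correlation and with fry, which asks only whether a list's genes move on balance in a direction. A count adjusted over the list alone used Benjamini-Hochberg adjustment on its members only.

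Replicate numbers were checked for pairing by the correlation of deviations from the group means. For 5-Ph-IAA and DMSO at 3 h these were 0.288, 0.347 and 0.647 for numbers 1, 2 and 3, and all 6 libraries correlated best with their own number, so these libraries were treated as pairs in an added fit. The pairing comes from this check and not from the labels, and the added fit uses the same libraries. Between 1.5 h and 3 h of 5-Ph-IAA, libraries of unlike number reached a correlation of 0.462. The check therefore cannot show that equal numbers mark pairs. In each other comparison at least 1 of the 3 correlations was under 0.1, so those libraries were not treated as pairs.

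The fits were tested on simulated data in which 67 genes changed 1.5-fold, 67 changed 2-fold and 66 changed 4-fold among 6069. For 5-Ph-IAA against DMSO at 3 h the test recovered 43.3%, 77.6% and 97% of them, and 6 of 151 calls were false. The simulation gave each gene the same spread in all groups and drew genes independently. The real 3 h libraries agreed less than the others, so the share of false calls need not hold for them. For 3 h against 1.5 h the shares were 22.4%, 76.1% and 97%, so small changes could be missed. Alternatives were DESeq2 1.42.0, RLE size factors, total counts alone, no filter, a mean of at least 10 CPM, only the compared groups, the replicate number as a block, robust estimation, a log2 change of at least 1, and leaving out each library. When a library is left out, its group keeps 2 and the spread is pooled over groups. Figures were drawn with Python 3.11.15 and matplotlib 3.10.9.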

Results

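Polyadenylated RNA was sequenced from the yeast Saccharomyces cerevisiae, strain W303, in which Zpr1 carried an auxin-inducible degron at its C terminus. Zpr1 is a chaperone that helps newly made translation elongation factor eEF1A to fold, and the degron lets the auxin derivative 5-Ph-IAA direct the tagged protein to the proteasome. The 15 libraries fell into 5 groups of 3, which were cells taken untreated at 0 h, cells treated with 5-Ph-IAA for 0.5 h, 1.5 h or 3 h, and cells given the solvent DMSO for 3 h. No strain without the degron was treated with 5-Ph-IAA, so the values below are those of compound and depletion together. DMSO was sampled at 3 h only, so differences from untreated cells at 0.5 h and 1.5 h also hold those of solvent and time in culture. Steps between times of 5-Ph-IAA also hold changes with time in culture and in solvent. Zpr1 protein was not measured in the files.

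The untreated libraries held 7892004, 9010837 and 9233290 counts, those at 0.5 h of 5-Ph-IAA 16599457, 12892710 and 6985793, and those at 1.5 h 8347962, 6465430 and 7419058. Depth was less even at 3 h, with 6297003, 2530145 and 17044914 counts under 5-Ph-IAA and 11374294, 21282576 and 15133126 under DMSO. Spearman correlations between replicates were 0.987 to 0.992 in untreated cells, 0.97 to 0.985 in DMSO and 0.954 to 0.975 at 3 h of 5-Ph-IAA. Library 3 of 5-Ph-IAA at 3 h correlated more with DMSO library 3 (0.984) and the 3 libraries at 1.5 h (0.976 to 0.982) than with its own replicates (0.969 and 0.954). Mitochondrially encoded genes held 0.786% (95% Wilson interval 0.779 to 0.793), 4.62% (4.59 to 4.64) and 0.0165% (0.0159 to 0.0171) of the counts of the 3 libraries of 5-Ph-IAA at 3 h. In DMSO they held 0.162% (0.16 to 0.165), 0.102% (0.1 to 0.103) and 0.0445% (0.0434 to 0.0456). Such intervals cover counting error only. Library 2 of 5-Ph-IAA at 3 h had both the lowest depth and the highest mitochondrial share, so counts of genes at 3 h are also given without it. All p-values measure only the spread between these libraries, since the labels do not say whether the replicates were separate cultures.

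The targeted gene came first. ZPR1 (YGR211W, R64 chromosome VII, 915241 to 916701) had 153 ± 32.3 CPM (counts scaled to library size, mean and SD, n = 3) in untreated cells, 289 ± 12.9 at 0.5 h, 240 ± 22 at 1.5 h and 124 ± 46.4 at 3 h of 5-Ph-IAA, against 94.6 ± 50.7 in DMSO. A degron acts on the protein, so these mRNA levels do not check the depletion. None of the differences from untreated cells passed the test, with adjusted p = 0.0864 at 0.5 h, 0.15 at 1.5 h and 0.485 at 3 h, and 0.0789 for DMSO. That in DMSO passed without DMSO library 3 (-1.21 log2, adjusted p = 0.00179) and with replicate number as a block (-0.78, adjusted p = 0.0397). When only the compared groups were fitted, ZPR1 rose by 0.95 log2 at 0.5 h (adjusted p = 0.000917) and by 0.68 at 1.5 h (adjusted p = 0.00312). The difference between 5-Ph-IAA and DMSO at 3 h was 0.41 log2 (SE 0.3, adjusted p = 0.47), and it passed with the 3 h libraries paired by replicate number (0.45, adjusted p = 0.0449) and without DMSO library 3 (0.92, adjusted p = 0.034).

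The genes of eEF1A were read next. TEF1 (YPR080W, chromosome XVI, 700594 to 701970) and TEF2 (YBR118W, chromosome II, 477671 to 479047) encode the same protein from near-identical sequences, so reads could be split between them in an unknown way. TEF1 went from 5590 ± 423 CPM in untreated cells to 4650 ± 499 at 0.5 h, 3810 ± 21.1 at 1.5 h and 2880 ± 139 at 3 h of 5-Ph-IAA. It fell against untreated cells at 1.5 h (-0.55 log2, SE 0.11, adjusted p = 0.00319) and 3 h (-0.96, adjusted p = 6.63e-06), and also in DMSO (-0.66, adjusted p = 0.000282), where it had 3540 ± 354 CPM. TEF1 did not pass between 5-Ph-IAA and DMSO at 3 h (-0.30, adjusted p = 0.115), but did with scaling on total counts alone (-0.36, adjusted p = 0.0319). TEF2 had 5130 ± 576 CPM untreated, 3830 ± 621 at 3 h of 5-Ph-IAA and 3470 ± 1070 in DMSO, and passed against untreated cells for DMSO (-0.56, adjusted p = 0.0287). That call ended with total counts (adjusted p = 0.088), with only the compared groups (0.0679) and without untreated library 2 (0.0718), untreated library 3 (0.129) or DMSO library 2 (0.101). At 3 h of 5-Ph-IAA TEF2 passed against untreated cells without 5-Ph-IAA library 3 (-0.55, adjusted p = 0.0451) and with replicate number as a block (0.0499) but under no other setting. Of the 8 genes of the list of eEF1A handling factors, none passed in edgeR or DESeq2 between 5-Ph-IAA and DMSO at 3 h, and 1 had an unadjusted p under 0.05.

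**Figure D1:**
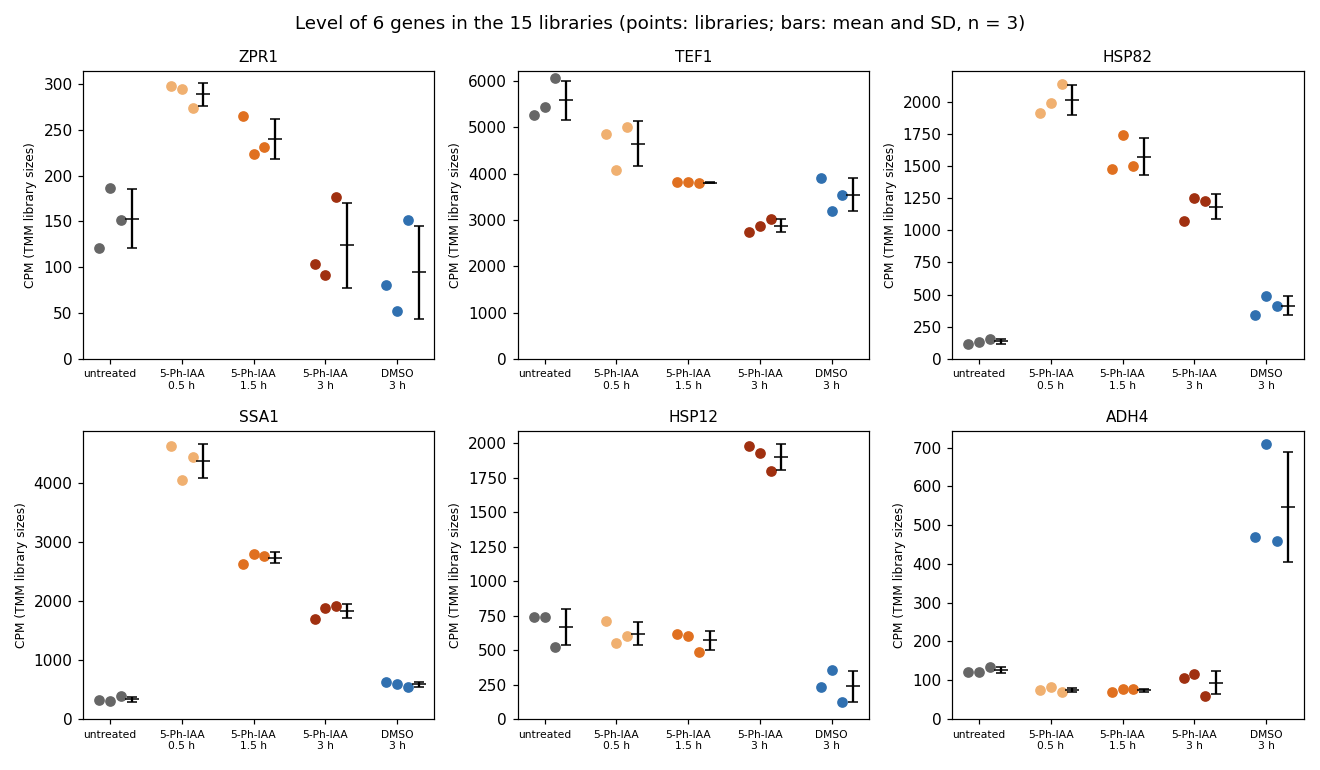
Level of 6 genes in CPM (linear axis from 0, TMM library sizes) in the 15 libraries by group, with points for libraries and bars for the mean and SD of 3. HSP82 and SSA1 stood highest at 0.5 h, with means of 2010 and 4370 CPM for HSP82 and SSA1, while ADH4 stood high in DMSO alone, at 546 CPM.

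The comparison of 5-Ph-IAA with DMSO at 3 h asks what the compound did beyond solvent and time in culture. Hsf1 targets stood out, such as HSP82 (YPL240C, chromosome XVI, 96496 to 98625), the stress-induced Hsp90, with 1180 ± 97.9 CPM against 411 ± 74.2, 2.88 times as much (1.53 log2, SE 0.14, adjusted p = 5.49e-06, n = 3 and 3). Of the 22 Hsf1 targets, genes that heat shock factor 1 switches on when proteins misfold, 19 rose over DMSO, 21 when adjusted over the list alone, and none fell. CUR1, a sorting factor for misfolded proteins, was 3.26 times as high (128 ± 7.54 CPM), the Hsp70 gene SSA1, which has the near-identical copy SSA2, was 3.12 times as high (1830 ± 114 CPM), and the mitochondrial disaggregase gene HSP78 was 2.56 times as high (571 ± 59.2 CPM). HSP60 (0.14 log2, adjusted p = 0.79) and HSP42 (0.64, adjusted p = 0.217) did not pass. The list test gave an adjusted p of 5.93e-44 at a median of 1.08 log2, and adjusted p = 0.00166 with an estimated correlation. The other chaperone lists were not called, and none of 16 genes of CCT chaperonin and prefoldin (1 at an unadjusted p under 0.05) or of 15 ribosome-linked chaperones and quality control genes (3) passed.

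Genes of amino acid synthesis were the other large group. Of 36 Gcn4 amino acid targets, which the activator Gcn4 turns on in amino acid starvation, 27 were higher than in DMSO, 33 when adjusted over the list alone, and none was lower (median 0.81 log2, list adjusted p = 2.77e-43, and adjusted p = 0.00405 with an estimated correlation). ORT1, the mitochondrial ornithine carrier, had 284 ± 21.4 CPM against 123 ± 4.9, 2.31 times as much. LEU4 of leucine synthesis was 2.27 times, LYS2 of lysine synthesis 2.15 times and GCV1 of the glycine cleavage system 2.32 times the DMSO level, while ARG1 (0.61 log2, adjusted p = 0.114) and ARO4 (0.65, adjusted p = 0.0514) did not pass. ZRT1 (chromosome VII, 20978 to 22108), the high-affinity zinc transporter, was lower under 5-Ph-IAA at 500 ± 155 CPM against 1400 ± 512 (-1.49 log2, SE 0.30, adjusted p = 0.0055). Of the 15 genes of the Zap1 zinc regulon, which is on in zinc shortage, 3 were lower, 5 when adjusted over the list alone, and none was higher (median -0.22, list adjusted p = 0.000103, and adjusted p = 0.036 with an estimated correlation). The 3 were ADH4, ZPS1 and ZRT1, and FET4 had -0.49 (adjusted p = 0.105).

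The 8 largest rises over DMSO were led by HSP12 (chromosome VI, 107256 to 107585), a membrane-protecting stress protein, at 1900 ± 95.2 CPM against 239 ± 113, 7.97 times as much (2.99 log2, SE 0.27, adjusted p = 4.14e-06). Against untreated cells HSP12 was higher under 5-Ph-IAA (1.51 log2) and lower in DMSO (-1.48). TMA10 was 5.18 times, the vitamin B6 synthesis gene SNZ1 4.92 times, and the hypoxic cytochrome c gene CYC7 4.43 times the DMSO level. ARO5 (YGL117W, chromosome VII, 288512 to 289309) was 4.36 times the DMSO level (389 ± 10.1 CPM against 89.2 ± 9.15, adjusted p = 8.52e-08), and YER053C-A 3.79 times. The adjacent genes YNR068C (chromosome XIV, 760067 to 760885) and BSC5 (761123 to 762592) were 5.08 and 3.78 times as high, at 64.9 ± 6.18 and 53.6 ± 9.98 CPM.

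The largest fall was that of ADH4 (chromosome VII, 15159 to 16307), an alcohol dehydrogenase gene of the zinc regulon, at 93.5 ± 29.6 CPM against 546 ± 142 (-2.56 log2, SE 0.21, adjusted p = 2.49e-06, n = 3 and 3). ZPS1, a cell surface gene induced by low zinc, had -1.99 log2 (adjusted p = 0.00606), and INO1, the inositol synthesis gene, had 29.3 ± 7.86 CPM against 105 ± 15.1 (-1.85, adjusted p = 0.00011). The others of the 8 largest falls were ZRT1, IMD2 (-1.41), YEL073C (-1.35), YMR085W (-1.15) and CSS1 (-1.08). IMD2, of guanine nucleotide synthesis, no longer passed when only the compared groups were fitted (adjusted p = 0.0632).

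Further lists were called at 3 h. Of 42 mitochondrial ribosomal proteins, all encoded in the nucleus, 14 were lower than in DMSO, 18 when adjusted over the list alone, and none was higher (median -0.40 log2, list adjusted p = 6.62e-15, but adjusted p = 0.0748 with an estimated correlation), with MRPL1 at -0.62, MRPL13 at -0.59, MRPL31 at -0.70 and MRPS9 at -0.64. The 14 became 8 without 5-Ph-IAA library 2 and 8 without DMSO library 1. Of 10 genes of the weak acid response, 5 were higher, among them the acid exporter gene PDR12 (1.68 times) and HSP30 (2.33 times), with YGP1 at -0.01 not passing (5 when adjusted over the list alone, list adjusted p = 0.000178, and adjusted p = 0.0827 with an estimated correlation), and 3 without DMSO library 1 or without DMSO library 2. Of 24 genes of Msn2/4 general stress, 4 were higher, including the catalase gene CTT1 (2.77 times) and NQM1 (2.35 times), 5 when adjusted over the list alone (list adjusted p = 0.000413, and adjusted p = 0.543 with an estimated correlation). Of 17 genes of cell wall integrity, 4 were higher, PIR3 at 2.3, PRM5 at 1.75, SED1 at 1.52 and BGL2 at 1.44 times DMSO, 5 when adjusted over the list alone (list adjusted p = 0.000178, and adjusted p = 0.098 with an estimated correlation).

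Ribosome genes differed little between 5-Ph-IAA and DMSO at 3 h. None of 138 cytosolic ribosomal proteins passed in edgeR (12 at an unadjusted p under 0.05, and 4 passed in DESeq2), nor did any of 30 genes of ribosome biogenesis (2 and 1), with list medians of -0.11 and -0.19 log2. These lists were called at adjusted p = 0.0119 and 0.00279, but adjusted p = 0.661 and adjusted p = 0.543 with an estimated correlation. The call of cytosolic ribosomal proteins ended without 5-Ph-IAA library 1 (adjusted p = 0.066) or DMSO library 1 (0.303), and that of ribosome biogenesis without DMSO library 1 (0.0674). With the 3 h libraries paired by number, 3 cytosolic ribosomal proteins and 4 genes of ribosome biogenesis were lower. Of 17 mitochondrially encoded genes, 5 passed as higher (12 when adjusted over the list alone, list adjusted p = 0.00279, and adjusted p = 0.575 with an estimated correlation), but none without 5-Ph-IAA library 2 (list adjusted p = 0.587) and none without any single DMSO library, and 15 without 5-Ph-IAA library 3.

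In all, 482 of 6069 tested genes passed edgeR's quasi-likelihood test between 5-Ph-IAA and DMSO at 3 h, 308 higher and 174 lower, and 122 of them differed at least by a log2 of 1. Without DMSO library 1 the count was 272, and without 5-Ph-IAA library 2 it was 324, with 303 of the 482 among them. The count was 151 when only the compared groups were fitted, whereas such fits raised the counts at 0.5 h (373 to 568) and 1.5 h (1068 to 1594). The main fit pools the spread over all 15 libraries, and replicates agreed less at 3 h than in the other groups. Its p-values for 5-Ph-IAA against DMSO at 3 h may therefore be too small, as may those of the other comparisons with a 3 h group. Fitting only the compared groups also lowered those counts. They went from 2385 to 1989 for 3 h of 5-Ph-IAA against untreated cells and from 2193 to 1870 for DMSO. For 3 h against 1.5 h of 5-Ph-IAA the count went from 961 to 631. Between 5-Ph-IAA and DMSO at 3 h the count was 820 with the 3 h libraries paired by replicate number. Scaling on total counts alone gave 507, of which 252 (49.7%, against 63.9%) were higher.

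**Figure D2:**
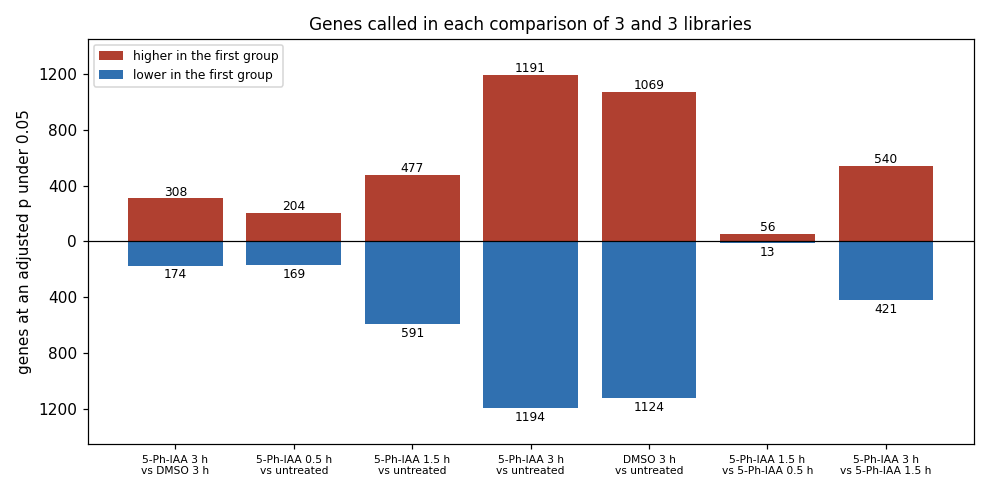
Number of genes at an adjusted p under 0.05 in the 7 comparisons of 3 and 3 libraries, with genes higher in the group named before "vs" drawn upward and lower ones downward. The comparisons of 3 h with untreated cells gave 1191 higher and 1194 lower genes for 5-Ph-IAA and 1069 and 1124 for DMSO.

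The comparison at 0.5 h against untreated cells asks what came soonest. Hsf1 targets rose steeply: BTN2 (chromosome VII, 772454 to 773686), a sorting factor for misfolded proteins, had 1060 ± 131 CPM against 70.2 ± 9.05 (15.1 times), and HSP82 had 2010 ± 120 against 134 ± 17 (15 times, 3.90 log2, SE 0.16, adjusted p = 6.86e-11, n = 3 and 3). SSA1 (chromosome I, 139503 to 141431) rose 12.9 times to 4370 ± 292 CPM and CUR1 (chromosome XVI, 843262 to 844020) 10.7 times to 213 ± 1.44. All 22 Hsf1 targets rose, also when adjusted over the list alone, with a median of 2.23 log2 (list adjusted p = 1.88e-206, and adjusted p = 5.86e-07 with an estimated correlation). The other chaperone lists were not called. None of 16 genes of CCT chaperonin and prefoldin passed (list adjusted p = 0.762). Of 15 ribosome-linked chaperones and quality control genes 3 rose, NPL4, CDC48 and UFD1 (list adjusted p = 0.388). The iron uptake genes FET3 (-2.06 log2, adjusted p = 0.00406) and SIT1 (-1.91, adjusted p = 0.00803) and the mating genes BAR1 (97.7 ± 11.7 against 263 ± 8.39 CPM, -1.43) and AGA1 (-1.42) had the largest falls. SIT1 no longer passed without 5-Ph-IAA library 2 (adjusted p = 0.0591).

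Of 33 genes of the proteasome list, 26 rose at 0.5 h, 32 when adjusted over the list alone, and none fell (median 0.53 log2, list adjusted p = 9.42e-24, and adjusted p = 0.0292 with an estimated correlation). RPN4, the activator of proteasome genes, rose 2.73 times, and the subunit genes PRE3, PRE1 and RPT1 rose 1.67, 1.66 and 1.58 times. The 26 of the proteasome list became 8, 12 and 7 without untreated library 1, 2 or 3, and 8, 8 and 17 without 5-Ph-IAA library 1, 2 or 3. Of 10 histones, 7 rose, 9 when adjusted over the list alone, among them HHT2 (1.69 times) and HTA2 (1.74 times), with an adjusted p = 0.0485 with an estimated correlation. The 7 histones became 4 without untreated library 1 or 3 and 4 without 5-Ph-IAA library 2 or 3.

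Mating genes and the M/G1 cluster fell at 0.5 h. Of 15 genes of the pheromone response, 8 fell, 10 when adjusted over the list alone, including FAR1 (-1.18 log2), which arrests the cycle in mating, and SST2 (-0.77). Of the 7 a-cell specific genes, 5 fell, 7 when adjusted over the list alone, such as AGA2 (-1.02) and the a-factor exporter gene STE6 (-0.69). Of 17 genes of the M/G1 cluster, 10 fell, 14 when adjusted over the list alone, including TEC1 (-0.90), MCM2 (-0.57) and the cyclin gene CLN3 (-0.57). These lists kept their calls at adjusted p = 0.00207, 0.00103 and 0.00207 with an estimated correlation. The 10 of the M/G1 cluster became 6 without 5-Ph-IAA library 2 or 3. Of 21 G1 cyclin and replication genes only PCL2, CDC6 and CLN2 fell, 6 when adjusted over the list alone (list adjusted p = 0.042, but adjusted p = 0.469 with an estimated correlation), and at most 2 on leaving out any single library. The mating lists and the M/G1 cluster also fell in DMSO at 3 h. Between 5-Ph-IAA and DMSO at 3 h only BAR1 and FAR1 of the pheromone response, BAR1 of the a-cell specific genes and MCM2, TEC1 and AMN1 of the M/G1 cluster were lower. The lists had adjusted p = 0.0292, 0.0244 and 0.0147 there, but adjusted p = 0.32, 0.098 and 0.098 with an estimated correlation. The 3 of the M/G1 cluster became 0 without 5-Ph-IAA library 2 or DMSO library 1.

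At 0.5 h, 373 genes passed, 204 higher and 169 lower. The count became 229 and 187 without untreated library 1 or 3, and 238, 178 and 224 without 5-Ph-IAA library 1, 2 or 3. It was 568 when only the compared groups were fitted. Scaling on total counts alone gave 407, of which 167 (41%, against 54.7%) were higher.

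The comparison at 1.5 h against untreated cells follows the response further. HSP82 was 11.7 times (1570 ± 141 CPM), SSA1 8.07 times (2730 ± 89.1) and CUR1 8.07 times (161 ± 8.21) the untreated level, and YNR068C, a gene without a standard name, rose 7.88 times (57.7 ± 6.04 against 7.32 ± 0.833 CPM, 2.98 log2, SE 0.18, adjusted p = 2.31e-08, n = 3 and 3). All 22 Hsf1 targets rose, also when adjusted over the list alone (median 1.84 log2, list adjusted p = 4.87e-102, and adjusted p = 2.07e-05 with an estimated correlation). The largest falls were those of FET3 (-2.73 log2), SIT1 (-2.37), EGO4 (-1.90, adjusted p = 0.0122) and AGA1 (-1.82). EGO4 no longer passed without untreated library 1 (adjusted p = 0.0515) or 5-Ph-IAA library 1 (0.0537).

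Genes for making ribosomes fell at 1.5 h. Of 30 genes of ribosome biogenesis, 25 fell, 28 when adjusted over the list alone, and none rose (median -0.62 log2, list adjusted p = 9.55e-15, but adjusted p = 0.0592 with an estimated correlation), with DBP10 at -0.78, NUG1 at -0.82, RRP5 at -0.69 and KRR1 at -0.74. Of 18 genes of RNA polymerase I and III, which make ribosomal and transfer RNA, 16 fell, 17 when adjusted over the list alone (RPC53 -0.91, RRN3 -0.69, RPA190 -0.65), with adjusted p = 0.0437 with an estimated correlation. Without 5-Ph-IAA library 2, ribosome biogenesis had 16 and RNA polymerase I and III had 10 lower genes.

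Of 36 Gcn4 amino acid targets, 11 rose at 1.5 h, 16 when adjusted over the list alone (list adjusted p = 5.46e-05, but adjusted p = 0.268 with an estimated correlation), including ARG4 (940 ± 2.83 against 479 ± 80.1 CPM, 1.96 times) and HIS5 (2.05 times), and 7 or 6 rose without untreated library 1 or 3. Of 10 genes of the weak acid response, 7 rose and 1, YGP1 (-0.76), fell, also when adjusted over the list alone (list adjusted p = 3.17e-05, but adjusted p = 0.0592 with an estimated correlation). TPO2, a polyamine exporter gene with the near-identical copy TPO3, rose 2.33 times, HRK1 1.84 times and PDR12 1.75 times. The pheromone response (10 of 15 fell, 11 when adjusted over the list alone), a-cell specific genes (5 of 7 fell, 7 when adjusted over the list alone) and the M/G1 cluster (11 of 17 fell, 14 when adjusted over the list alone) each held at adjusted p = 0.00296 with an estimated correlation, and they fell in DMSO at 3 h too. The 11 of the M/G1 cluster became 7 without untreated library 3 or 5-Ph-IAA library 1 or 2. In all 1068 genes passed at 1.5 h, 477 higher and 591 lower, but 582 without untreated library 3 and 645 or 577 without 5-Ph-IAA library 1 or 2. On total counts alone 1000 passed, of which 585 (58.5%, against 44.7%) were higher.

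**Figure D3:**
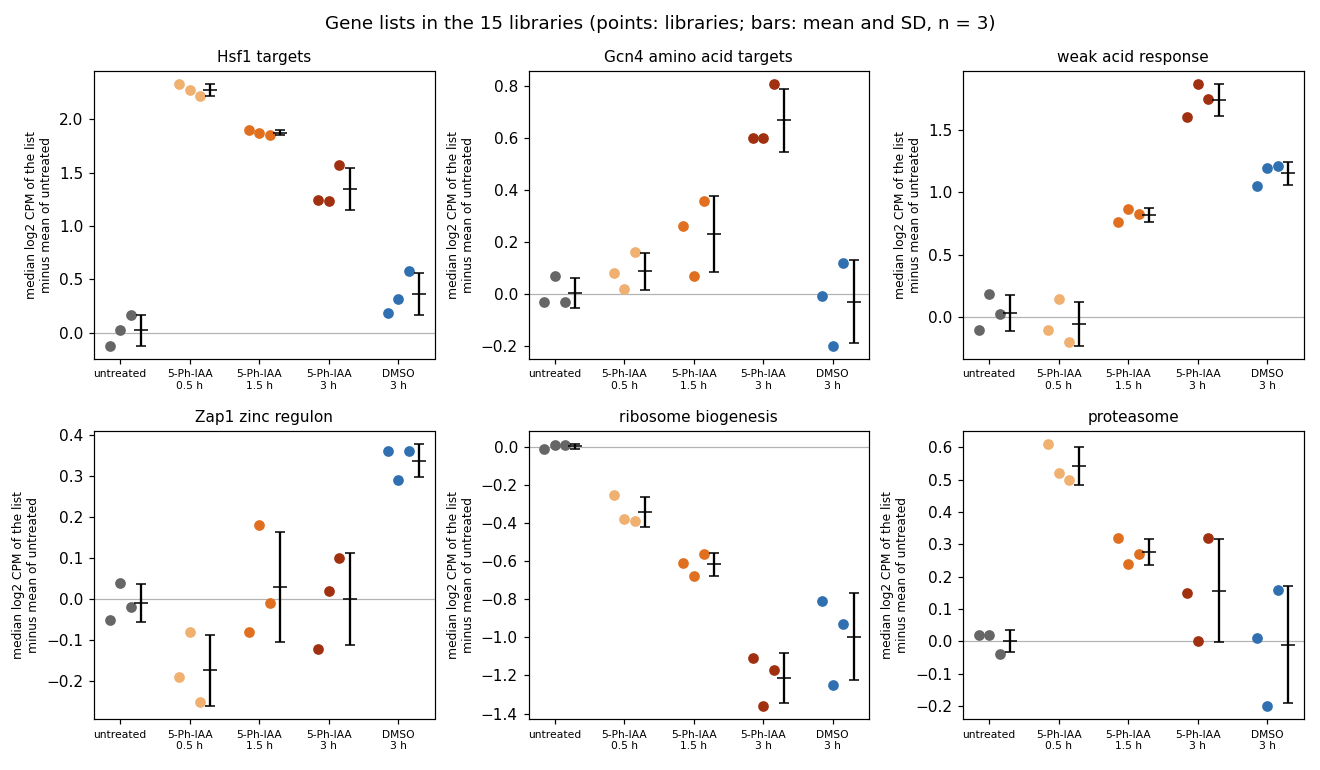
Median over each gene list of the log2 CPM minus the mean of untreated cells, per library, in the 5 groups, with points for libraries and bars for the mean and SD of 3. The 3 libraries of Hsf1 targets lay at 2.22 to 2.33 at 0.5 h, 1.85 to 1.90 at 1.5 h and 1.23 to 1.57 at 3 h of 5-Ph-IAA, and at 0.19 to 0.58 in DMSO.

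At 3 h of 5-Ph-IAA against untreated cells, treatment and time in culture act together. HSP78 was 9.01 times (571 ± 59.2 against 63.4 ± 14.2 CPM, 3.17 log2, SE 0.16, adjusted p = 6.68e-10, n = 3 and 3), YNR068C 8.85 times, HSP82 8.81 times, and HSP30, a plasma membrane stress gene, 8.45 times (426 ± 35.1 against 50.5 ± 21.4) the untreated level. The largest falls were those of the iron uptake genes FET3 at -2.93 (41.8 ± 8.94 against 320 ± 53.6 CPM), SIT1 at -2.45, FRE1 at -2.05 and FTR1 at -1.95. Of 20 genes of the Aft1 iron regulon 8 fell, also when adjusted over the list alone, and none rose (median -0.50 log2, list adjusted p = 0.00139, but adjusted p = 0.282 with an estimated correlation). FTH1 (-0.24, adjusted p = 0.22) did not pass. In DMSO 9 of the 20 fell (list adjusted p = 0.00478, but adjusted p = 0.335 with an estimated correlation). Of 22 Hsf1 targets 21 rose, also when adjusted over the list alone, YDJ1 being the exception (0.33, adjusted p = 0.19), with adjusted p = 0.00595 with an estimated correlation. All 30 genes of ribosome biogenesis fell, also when adjusted over the list alone (DBP10 -1.33, KRR1 -1.38, NUG1 -1.44, median -1.17), and so did all 18 of RNA polymerase I and III, each list with adjusted p = 0.0174 with an estimated correlation.

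Of 138 cytosolic ribosomal proteins, 112 fell at 3 h of 5-Ph-IAA, 119 when adjusted over the list alone (median -0.56 log2, list adjusted p = 8.42e-14, but adjusted p = 0.159 with an estimated correlation), such as RPL33B (-0.90) and RPL14B (-0.83). Of 10 genes of the weak acid response 8 rose, 9 when adjusted over the list alone (median 1.76, adjusted p = 0.00595 with an estimated correlation), TPO2 6.77 times, YRO2 5.65 times and PDR12 4.25 times. Of 36 Gcn4 amino acid targets 25 rose, also when adjusted over the list alone (median 0.69, list adjusted p = 1.92e-12, but adjusted p = 0.0681 with an estimated correlation), with HIS4 at 3.49 and ARG4 at 3.42 times. Of 24 genes of Msn2/4 general stress 19 rose and 1, HSP26 (-1.71), fell, also when adjusted over the list alone (list adjusted p = 1.16e-08, but adjusted p = 0.169 with an estimated correlation), with the trehalose synthesis genes TSL1 at 3.48 and TPS2 at 2.69 times and the glucokinase gene GLK1 at 3.5 times. With an estimated correlation 7 lists kept their call at 3 h of 5-Ph-IAA against untreated cells, not all of them described here. Counted without direction, 10 of 15 genes of the pheromone response, 6 of 7 a-cell specific genes and 13 of 17 of the M/G1 cluster passed. In all 2385 genes passed, 1191 higher and 1194 lower, and 2068 without 5-Ph-IAA library 2. On total counts alone, which moved the median of all genes to 0.15 log2, 2401 passed, 1557 of them (64.8%, against 49.9%) higher.

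DMSO at 3 h against untreated cells shows what changed with solvent and time and no 5-Ph-IAA. YEL073C rose 12.5 times (77.2 ± 19.7 against 6.22 ± 2.52 CPM, 3.64 log2, SE 0.27, adjusted p = 3.62e-07, n = 3 and 3), and the zinc genes ZPS1 and ZRT1 rose 8.94 times (458 ± 102 against 51.2 ± 11.8) and 7.2 times (1400 ± 512 against 195 ± 82.4). ENO1, the enolase gene of glycolysis, rose 7.55 times (2240 ± 61.7 against 297 ± 54.8). The largest falls were in the small heat shock gene HSP26 (-2.73), SIT1 (-2.07), FET3 (-1.90) and SHC1 (-1.86). Of 15 genes of the Zap1 zinc regulon 8 rose and 1 fell, also when adjusted over the list alone (list adjusted p = 0.00265, but adjusted p = 0.0699 with an estimated correlation), with ADH4 at 4.33 and the regulator gene ZAP1 at 2.73 times.

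Ribosome genes fell with DMSO too. Of 30 genes of ribosome biogenesis 27 fell, 30 when adjusted over the list alone (median -0.97 log2), and all 18 of RNA polymerase I and III fell, also when adjusted over the list alone, each list with adjusted p = 0.0241 with an estimated correlation. Of 138 cytosolic ribosomal proteins 91 fell and 1 rose (108 and 2 when adjusted over the list alone, list adjusted p = 5.23e-11, but adjusted p = 0.211 with an estimated correlation), but 52 fell without untreated library 3 and 38 on total counts alone. Of 22 Hsf1 targets 9 rose, including HSP104 (3.94 times), HSP78 (3.52 times) and HSP82 (3.06 times), while HSC82 (0.28, adjusted p = 0.149) did not pass; adjusted over the list alone 10 rose and 1 fell, with list adjusted p = 8.84e-05 but adjusted p = 0.192 with an estimated correlation, and 14 rose on total counts alone. Of 42 mitochondrial ribosomal proteins 25 rose, 31 when adjusted over the list alone, such as MRPL22 (1.59 times) and MRPL1 (1.42 times), with list adjusted p = 5.54e-06 but adjusted p = 0.211 with an estimated correlation. Of 20 genes of the unfolded protein response 10 rose, also when adjusted over the list alone, and of 10 genes of the weak acid response 9 rose, also when adjusted over the list alone, each with adjusted p = 0.0241 with an estimated correlation. In DMSO 10 of 15 genes of the pheromone response, 6 of 7 a-cell specific genes and 10 of 17 genes of the M/G1 cluster fell, and 11, 6 and 10 did when adjusted over the list alone. AGA1 had -1.45, SST2 -1.02, MFA1 -1.70 and TEC1 -0.75. The lists had adjusted p = 0.0292, 0.0241 and 0.0459 with an estimated correlation. On total counts alone 4 of the M/G1 cluster fell. Of 21 genes of autophagy 13 rose, such as ATG8 (2.56 times), and 15 did when adjusted over the list alone. Autophagy had adjusted p = 0.0459 with an estimated correlation. Of 36 Gcn4 amino acid targets 5 rose and 8 fell in DMSO and the list was not called, and on total counts alone 11 rose and 3 fell.

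In all 2193 genes passed between DMSO and untreated cells, 1069 higher and 1124 lower. On total counts alone the median of all genes was at 0.21 log2 and 2402 passed, 1782 of them (74.2%, against 48.7%) higher. Changes from untreated cells at 3 h correlated across genes between 5-Ph-IAA and DMSO at r = 0.733, with 741 genes higher and 874 lower in both, where independent lists would share 210 and 221. Both comparisons used the same untreated libraries, and 20 simulations of unchanged groups against such controls gave a mean r of 0.499. The covariance was 0.299 against 0.0328 simulated. Untreated libraries could not be divided into parts of 2 or more, so part of the excess may come from shared controls.

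Between 0.5 h and 1.5 h of 5-Ph-IAA few genes changed. TDA6, which lies next to CUR1, rose 4.74 times (50.8 ± 12.6 against 10.7 ± 3.28 CPM, 2.24 log2, SE 0.26, adjusted p = 0.000373, n = 3 and 3), HSP30 3.78 times, STP4, a zinc finger gene, 3.38 times, and CIP1 3.08 times. Falls were smaller, with PRM7 at -1.15, BTN2 at -0.98, PYC1 at -0.79 and YGR079W at -0.70. PRM7 and BTN2 did not pass without any single one of the 6 libraries (adjusted p of 0.0526 to 0.201 for PRM7 and 0.0813 to 0.177 for BTN2), and BTN2 not on total counts alone (0.0535). PYC1 did not pass without 5-Ph-IAA 0.5 h library 1 (0.0584) or 3 (0.139) or 1.5 h library 1 (0.104), 2 (0.133) or 3 (0.0526), nor YGR079W without 0.5 h library 1 (0.0657) or 3 (0.075) or 1.5 h library 2 (0.108) or 3 (0.0526).

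Of 10 genes of the weak acid response 4 rose from 0.5 h to 1.5 h, 6 when adjusted over the list alone (list adjusted p = 1.67e-13, and adjusted p = 0.00854 with an estimated correlation). Of 22 Hsf1 targets 3 fell, 11 when adjusted over the list alone, BTN2, SSA1 (-0.68) and CPR6 (-0.65) being the 3 (list adjusted p = 2.14e-11, but adjusted p = 0.0976 with an estimated correlation). The 3 Hsf1 targets became 0 without 0.5 h library 1 or 1.5 h library 1, and 1 without 0.5 h library 2 or 3, without 1.5 h library 2 or 3, or on total counts alone. In all 69 genes passed, 56 higher and 13 lower, but 27, 42 and 23 without 0.5 h library 1, 2 or 3 and 30, 24 and 37 without 1.5 h library 1, 2 or 3. DESeq2 gave 165, the fit of only the compared groups 222, and total counts alone, with the median of all genes at 0.11 log2, gave 115, of which 110 (95.7%, against 81.2%) were higher.

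Between 1.5 h and 3 h of 5-Ph-IAA genes of the weak acid response rose. This step is not matched for solvent and time in culture. In DMSO at 3 h against untreated cells 9 of the 10 genes of the weak acid response rose. There 17 of the 24 genes of Msn2/4 general stress passed, counted without direction, while of 36 Gcn4 amino acid targets 5 rose and 8 fell. Of 10 genes of the weak acid response 8 rose, also when adjusted over the list alone, PDR12 2.43 times and YGP1 2.1 times (median 1.18 log2, list adjusted p = 3.21e-14, and adjusted p = 0.00664 with an estimated correlation). Of 24 genes of Msn2/4 general stress 16 rose, 18 when adjusted over the list alone, such as TSL1 (3.56 times), SPI1 (3.46 times) and DCS2 (3.02 times). Of 36 Gcn4 amino acid targets 18 rose, 23 when adjusted over the list alone, such as HIS4 (1140 ± 92.8 against 478 ± 64.8 CPM, 2.39 times, 1.25 log2, SE 0.13, adjusted p = 3.57e-05, n = 3 and 3) and GCV1 (2.34 times). Both these lists were called, at adjusted p = 1.88e-19 and 1.15e-12, but each had adjusted p = 0.116 with an estimated correlation.

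Of 22 Hsf1 targets 13 fell from 1.5 h to 3 h, 16 when adjusted over the list alone while 1 rose, such as SSA1 (-0.58) and YDJ1 (-0.84), with list adjusted p = 2.21e-07 but adjusted p = 0.116 with an estimated correlation. The 13 Hsf1 targets became 4, 7 and 6 without 1.5 h library 1, 2 or 3 and 6 and 5 without 3 h library 1 or 2. Of 30 genes of ribosome biogenesis 21 fell, 26 when adjusted over the list alone (list adjusted p = 1.37e-15, but adjusted p = 0.116 with an estimated correlation), but 13 without 1.5 h library 3 and 12 without 3 h library 2. Of 138 cytosolic ribosomal proteins 49 fell, 94 when adjusted over the list alone (list adjusted p = 3.95e-19, but adjusted p = 0.116 with an estimated correlation). The 49 cytosolic ribosomal proteins became 17, 17 and 23 without 1.5 h library 1, 2 or 3, 30 and 9 without 3 h library 1 or 2, and 31 on total counts alone.

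The 4 largest rises from 1.5 h to 3 h were in RRT15 (172 ± 282 against 0.444 ± 0.127 CPM), which matches ribosomal RNA copies, and the small nucleolar RNAs SNR30 (936 ± 1340 against 41.5 ± 10.8), SNR63 (318 ± 465 against 19.7 ± 1.4) and SNR11 (164 ± 233 against 11.3 ± 0.935). Their SD exceeded their mean, and small nucleolar RNA took 1.82% (95% Wilson interval 1.8 to 1.84) of the counts of 3 h library 2 against 0.251% (0.247 to 0.255) and 0.0861% (0.0848 to 0.0875) in libraries 1 and 3. SNR11 no longer passed without that library (adjusted p = 0.0822), nor did SNR11 and SNR63 when only the compared groups were fitted (adjusted p = 0.0563 for each). The largest falls were those of the biotin synthase gene BIO2 (-1.06), IZH4 (-1), DHR2, a helicase gene of ribosome synthesis (-0.99), and ZPR1 (-0.94, adjusted p = 0.0436). IZH4 did not pass without 1.5 h library 3 (adjusted p = 0.102), without 3 h library 2 (0.0707) or with only the compared groups (0.0523). ZPR1 did not pass in DESeq2 (0.0532), on total counts (0.0544), with robust estimation (0.0674) or without 1.5 h library 1 (0.135), 2 (0.0816) or 3 (0.0906) or 3 h library 1 (0.14) or 2 (0.173). TEF1 passed at -0.41 (adjusted p = 0.0208), but not with only the compared groups (0.0628) or without 1.5 h library 1 (0.0714), 2 (0.0623) or 3 (0.0682) or 3 h library 1 (0.0651) or 2 (0.0883).

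In all 961 genes passed between 1.5 h and 3 h of 5-Ph-IAA, 540 higher and 421 lower. The count was 532, 626 and 602 without 1.5 h library 1, 2 or 3, 523 without 3 h library 2, and 631 with only the compared groups. On total counts alone 889 passed, of which 608 (68.4%, against 56.2%) were higher. Over untreated cells and the 3 times of 5-Ph-IAA together, 2254 genes (37.1% of those tested) changed at some time.

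The changes at 1.5 h against untreated cells and at 3 h against DMSO share no library, and across genes, which are not independent replicates, they correlated at r = 0.054 (Spearman 0.189). Of the genes that passed in both, 101 were higher in both, where independent lists would share 24.2, and 32 were lower in both against 16.9. A further 34 were higher at 1.5 h and lower at 3 h against DMSO, where independent lists would share 13.7, and 7 were lower at 1.5 h and higher at 3 h against DMSO, where they would share 30. The correlation turned to -0.026 without 5-Ph-IAA 3 h library 3 and became 0.208 without 3 h library 2 and 0.111 without DMSO library 3. The changes at 0.5 h and 1.5 h, which share the untreated libraries, correlated at r = 0.711, against 0.506 in the simulation of unchanged groups, with covariances of 0.121 and 0.0332. They had 153 genes higher in both and 136 lower in both, where independent lists would share 16 and 16.5. The changes at 0.5 h against untreated cells and at 3 h against DMSO, which share no library either, correlated at r = 0.261 (Spearman 0.186), with 51 genes higher in both against 10.4, 15 lower in both against 4.85, 10 higher then lower against 5.85 and 9 lower then higher against 8.58.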

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

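The tests of poly(A) selection, with the values of RRT15, and of an effect in every library, in the paragraph on mitochondrially encoded RNA, were chosen only after the result was seen. Between time points of 5-Ph-IAA, 69 genes differed from 0.5 h to 1.5 h and 961 from 1.5 h to 3 h, each a tested difference of the effects against untreated cells. The same differences called 16 gene lists from 0.5 h to 1.5 h and 17 from 1.5 h to 3 h, of which 1 and 1 kept the call with an estimated correlation.

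Mitochondrially encoded genes, outside the polyadenylated nuclear messages the study measured, took 0.324% of the counts of 5-Ph-IAA 0.5 h library 3, 0.786% of 3 h library 1 and 4.62% of 3 h library 2, above the 0.162% of DMSO library 1, the highest of the untreated and DMSO libraries. An effect of 5-Ph-IAA in every library is argued against by library 3 of the 3 h group, at 0.0165%, below the lowest DMSO library at 0.0445%. Over the 15 libraries the mitochondrial share went with the small nucleolar share (Spearman 0.943, Pearson 0.996, permutation p = 1e-05 for each, the smallest the permutations can give, adjusted 3e-05 over 3 relations for Spearman), and Pearson was 0.769 without the 2 farthest libraries. Incomplete poly(A) selection in single libraries may raise both. All genes annotated as ribosomal RNA took 3.85% of 3 h library 2, so most of its mitochondrial share was ribosomal RNA. The nuclear ribosomal RNA share, at most 0.00142%, gave a lowest Spearman of 0.143 (permutation p = 0.61). It rested on as few as 36 counts in a library, and the treatment of reads with several matches is unknown, so it cannot decide. RRT15, which matches ribosomal RNA copies, took 0.0507% of 3 h library 2, 0.00199% of library 3, where the mitochondrial share was low, and 6.35e-05% of library 1. Incomplete poly(A) selection therefore stays open. A difference between the cultures in mitochondrial RNA also stays open and was not tested.

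For 5-Ph-IAA against DMSO at 3 h, 2 of the 10 splits of the 6 libraries into 3 and 3 gave as many genes as the real 482, the highest other split giving 585. That split set 5-Ph-IAA libraries 1 and 2 with DMSO library 2 against the rest, so a structure of the samples other than treatment is at least as large. The real split and 3 others part all 3 pairs of equal number, and those 3 others called 0 genes each, while the split with 585 parts 1 pair. The fit paired by replicate number called 820 genes. For each of the other 6 comparisons of 3 and 3, 1 of 10 splits, the real one, gave as many genes, with 0 as the highest other against real counts of 373, 1068, 2385, 2193, 69 and 961. The 10 splits are too few for a share under 0.05. For the time course 1 of 100 splits of 12 libraries, the real one, gave as many genes as the real 2254, the highest other being 948. That share is the smallest that 100 splits can give and argues against a chance division of the libraries. It cannot exclude differences between cultures, since the labels do not say whether replicates were separate cultures.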

How the results depend on the processing

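The fits that paired only the 3 h libraries or only the compared groups at 3 h, and those without genes of ribosomal, mitochondrial and small RNA, were chosen only after the data were seen. Unless a library or setting is named as the difference, the cause was not tested. The 84 named results checked were those of ZPR1, TEF1, TEF2 and the largest rises and falls, not those of members named from lists. Of their alternatives, 1234 kept direction and side of the threshold, 51 no longer passed, 9 newly passed and none reversed. Of the alternatives of counts and correlations, 190 stayed close, 46 moved and 1 reversed.

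For 5-Ph-IAA against DMSO at 3 h the 482 genes became 151 with only the compared groups, 122 at a log2 change of at least 1 and 272 (without DMSO library 1) to 562 (without 5-Ph-IAA library 3) on leaving out a library, with 663 in DESeq2, which shared all 482. At 0.5 h the 373 became 568 with only the compared groups, 83 at a log2 of 1, and 178 to 274 on leaving out a library. At 1.5 h the 1068 became 140 at a log2 of 1 and 577 to 851. At 3 h against untreated cells 2385 became 666 and 1947 to 2279, and for DMSO 2193 became 396 and 1707 to 2250. From 0.5 h to 1.5 h the 69 became 165 in DESeq2, 115 on total counts, 222 with only the compared groups, 18 at a log2 of 1 and 23 to 42. From 1.5 h to 3 h the 961 became 631 with only the compared groups, 177 at a log2 of 1 and 523 to 1287. The time course stayed at 1846 to 2321 without single libraries. A stricter fold size lowers a count by construction. Lists called with an estimated correlation were 3 for 5-Ph-IAA against DMSO, 7, 5 and 7 for 0.5 h, 1.5 h and 3 h against untreated cells, 8 for DMSO, and 1 and 1 for the steps between times. With fry 12 lists were called for 5-Ph-IAA against DMSO and 7 from 0.5 h to 1.5 h. The correlation of 0.054 between the changes at 1.5 h and those at 3 h against DMSO was 0.189 by rank, and reversed to -0.026 without 5-Ph-IAA 3 h library 3, with 0.208 as the highest. Without genes of ribosomal, mitochondrial and small RNA the counts were 473, 401, 1107, 2327, 2219, 82, 901 and 2255.

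Replicate number as a block in all groups gave 483 genes for 5-Ph-IAA against DMSO, then 407, 1114, 2429, 2246, 75 and 1033 for the other comparisons, 2297 for the time course, 18, 17, 23, 25, 26, 16 and 19 lists, and a correlation of 0.084. The block for the 3 h libraries alone gave 820 genes, 462 of them among the 482, with 19 lists, or 3 with an estimated correlation, and with only the compared groups the block gave 555. In that paired fit G1 cyclin and replication genes lost their call (adjusted p = 0.0625 from 0.0398), translation initiation factors gained one (0.0383 from 0.0618) and ZPR1 passed. It changed no other call of a list, nor any of TEF1, TEF2 or the largest rises and falls. Members named from lists were not checked in that fit. In the other comparisons libraries were not treated as pairs. The pair correlations at 0.5 h against untreated were 0.094, -0.027 and 0.06. At 3 h of 5-Ph-IAA against untreated they were 0.417, 0.042 and 0.091, where 5 of 6 libraries correlated best with their own number. Under the block TEF2 at 3 h (adjusted p = 0.0499) and ZPR1 in DMSO (0.0397) newly passed. Depth limits what can be seen in 5-Ph-IAA 3 h library 2, with 2530145 counts.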

Other observations

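The lists of phospholipid synthesis and mitochondrial synthetase genes and the test of cultures less advanced were chosen only after the result was seen. Genes of phospholipid and inositol synthesis were higher in DMSO at 3 h than in untreated cells, and part of them were lower with 5-Ph-IAA than in DMSO at 3 h. Of 20 such genes 16 rose in DMSO at 3 h against untreated cells, 16 when adjusted over the list alone, with a median of 1.08 log2, and 11 rose under 5-Ph-IAA at 3 h with a median of 0.38. OPI3, of phosphatidylcholine synthesis, had 206 ± 52.4 CPM (SD, n = 3) in untreated cells, 1210 ± 60.6 in DMSO and 607 ± 113 under 5-Ph-IAA (-0.99 log2 against DMSO, SE 0.21, adjusted p = 0.0077). The inositol transporter gene ITR1 had 403 ± 103, 1880 ± 98.4 and 1170 ± 50.2 CPM in the same groups, and the regulator gene INO2 had 19.8 ± 5.37, 41.1 ± 5.11 and 23.7 ± 1.75, but 42.4 ± 4.83 at 1.5 h of 5-Ph-IAA. Against DMSO 9 of the 20 were lower, 12 when adjusted over the list alone, and none was higher, while CHO2 (-0.31, adjusted p = 0.278) did not pass. The 9 became 6 without DMSO library 2, 7 without DMSO library 3 or 5-Ph-IAA library 1 or 2, and 11 on total counts alone. At 1.5 h 14 of the 20 had risen over untreated cells, where INO1 (-0.40, adjusted p = 0.267) did not pass.

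Of 13 nuclear genes of mitochondrial aminoacyl-tRNA synthetases, 12 rose in DMSO at 3 h against untreated cells, also when adjusted over the list alone (median 0.70 log2), and 4 rose under 5-Ph-IAA (MSF1, MSK1, MSW1 and MST1, median 0.25), which became 2 without untreated library 2 or 5-Ph-IAA library 3. Against DMSO 6 were lower, 9 when adjusted over the list alone, such as NAM2 (-0.69, SE 0.11, adjusted p = 0.00125) and MSK1 (59.4 ± 1.56 against 91.6 ± 0.328 CPM, -0.63, adjusted p = 0.00267). The 6 became 3 without 5-Ph-IAA library 2 or DMSO library 1, and both lists were picked partly from genes seen to differ, so their counts are not independent evidence.

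Some genes held the same direction at 0.5 h and 1.5 h against untreated cells and at 3 h against DMSO. There were 49 higher each time, 19 of them Hsf1 targets and 23 in no list, and 15 lower each time. A further 7 were higher at 0.5 h and 1.5 h but lower against DMSO. Another 2 were lower at 0.5 h and 1.5 h but higher against DMSO, and 2 were lower at 0.5 h only and then higher. The comparisons at 0.5 h and 1.5 h share the untreated libraries, so their agreement is not independent. The genes ROQ1, SSE1, SGT2, TMC1 and UBI4 were among the 23, and BAR1, FAR1 and ASH1 among the 15, all chosen after their values were seen.

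The zinc regulon at 3 h, where ADH4, ZPS1 and ZRT1 were lower under 5-Ph-IAA than in DMSO, was weighed against cultures less advanced with 5-Ph-IAA than with DMSO. In that case genes that moved between untreated cells and DMSO should go back towards untreated cells. Of 239 genes outside the zinc regulon that passed in both comparisons, 62.3% changed in the direction opposite to their change in DMSO. Only direction was counted, so a gene that went beyond its untreated level was counted as going back too. The 62.3% held all 13 mitochondrial ribosomal proteins, but all 5 of the weak acid response and all 8 Hsf1 targets went further. Cultures less advanced therefore cannot be told apart from an effect on the zinc genes. Both comparisons share the DMSO libraries, which by itself raises the share going back above the 50.4% of unrelated directions. With 1 DMSO library against untreated cells and the other 2 against 5-Ph-IAA it was 58.6%, 40.2% and 43.3% for libraries 1, 2 and 3. The 5-Ph-IAA library of equal number, whose deviations went with those of that DMSO library, stayed in the second comparison, which lowers the share. These shares therefore cannot be set cleanly against unrelated directions. This test took the place of an earlier one, on the weak acid response and ribosome biogenesis alone. In that test all 5 genes that passed went further from untreated cells. They were the same 5 genes of the weak acid response, and no gene of ribosome biogenesis passed in both comparisons. The earlier test had argued against cultures less advanced, and the change was made after that outcome was known. That 1 library decides the fall is argued against at the preset correlation, since over the 6 fits that each left out a library the list's adjusted p was at most 0.00182, with at least 3 members lower in each, but its median of -0.22 log2 ranged from -0.15 to -0.40, the lowest without 5-Ph-IAA library 3, and these fits were not run with an estimated correlation.

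A hypothesis was that neighbours of Hsf1 targets rise with them at 0.5 h. Over 43 neighbours the median was 0.09 log2, at percentile 99.6 of 10000 random lists matched on expression, so as a set they stood above ordinary genes, although 4 rose and 5 fell. The 7 neighbours that share a divergent promoter region had a median of 0.37, and 3 rose, LST8 next to SIS1 (1.25 log2, adjusted p = 6.39e-07), MTQ1 next to YDJ1 (0.68) and LCB5 next to HSP60 (0.47), which were chosen after their values were seen. For read-through into the gene downstream on the same strand, 12 such genes differed in median by -0.39 from the divergent ones (one-sided permutation p = 0.986). The divergent ones had the highest median of all types, so this comparison cannot decide. The median of the 12 was -0.02, against 0.01 for the 15 upstream genes on the same strand. None of the 12 rose and 2 fell, so a rise by read-through was not seen. For the 9 convergent genes the difference was -0.27 (one-sided permutation p = 0.808), and YDR215C next to AHA1 (2.33) rose, so an overlap of 3' ends counted without strand could not be ruled out.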
